A study of Mus musculus with 6 samples.

How the data were processed

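The samples were 6 left ventricles of mice on cyclosporin for 3 weeks, 3 WT and 3 with the R719W mutation in Myh6. Per the labels' protocols, total RNA was isolated with a kit that retains small RNAs, and multiplexed miRNA libraries were prepared. The aligner, the number of mismatches allowed, the miRNA annotation release and the genome build used to count the reads are not given in the sources used here. The authors deposited 2 tables, 1 per genotype, both listing the same 698 mature miRNAs by name and sequence. Per the file headers, each table holds read counts for each library, whole numbers with no normalization, and a normalized value. The authors' normalized value equals CPM: the read count as a share of the library's total over the listed miRNAs, on the CPM scale, within a relative gap of 4.6e-15. Table columns were assigned to samples by the barcode named in both the header and the sample's description. Levels of different miRNAs within one library also reflect how well each sequence is ligated and amplified, so they are less comparable than levels of one miRNA between libraries. Multiplexed small-RNA reads count only miRNAs relative to each other, so a change in one abundant miRNA shifts the share of all others.

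Read counts were analysed in R 4.3.3 with edgeR 4.0.16. miRNAs were kept by filterByExpr on genotype (minimum count 10, total 15), which kept miRNAs holding at least 99.9% of the reads of each library and left 517 of the 698 untested. Counts were scaled by TMM (factors 0.83 to 1.22), and R719W was compared with WT by glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over all miRNAs tested and calls at an adjusted p below 0.05. The biological coefficient of variation was 22.5%. Fold changes are R719W over WT, standard errors are the absolute log2 fold change divided by the square root of the F statistic, and levels are TMM-normalised CPM with the SD over 3 libraries. Names of arms, including the asterisk, are those of the tables. A total of 22 miRNA lists were fixed before the data were examined: muscle, myosin intron, raised and lowered in hypertrophic hearts, the miR-29, miR-30, let-7, miR-15 and miR-16, miR-34 and miR-449, miR-181, and miR-10, miR-99 and miR-125 families, the miR-17 and miR-92 and the miR-23, miR-27 and miR-24 clusters, Dlk1-Dio3, and markers of fibroblasts, smooth muscle, endothelium, leukocytes, erythroid cells, neurons, epithelium and liver. The 16 lists with at least 3 tested entries were tested with camera of limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over the 16). Entries joined a list by name whichever their arm, so a role named for a family need not hold for its entries with an asterisk. The lists overlap: the hypertrophy lists hold fibroblast, miR-30, miR-29 and muscle entries. Shares of reads and numbers of detected miRNAs were compared by exact permutation tests, two-sided, for which 3 against 3 libraries allow no p below 0.1.

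The miRNAs named were chosen by a rule fixed before the data were examined. It took the 12 with the largest positive and the 12 with the largest negative log2 fold change among called miRNAs without overlap between genotypes, miR-208a, miR-208b, miR-499, miR-1, miR-133a, miR-21, the miR-29 family and the miR-199a and miR-214 entries whatever their p, and the 10 most abundant. It further took up to 4 members with the smallest p of each called list, and up to 2 of the most abundant members of each other list. Alternatives tried were DESeq2 1.42.0 in place of edgeR, DESeq2's size factors, library totals alone and totals without the 5 most abundant miRNAs in place of TMM, no filter on low counts, a filter of 100 reads in 3 libraries, limma on log2 of the deposited CPM value plus 1, 0.5 or 10, camera with an estimated correlation, fry, the replicate number as a block, and leaving out each library in turn. The design text names no test.

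Replicates of a genotype differed beyond sampling noise in each pair (chi-square per degree of freedom 35.8 to 350), and Spearman correlations lay between 0.954 and 0.991. Mature sequences were matched to hairpins in GENCODE M21 (GRCm38): 659 of 698 matched a hairpin, 588 of them a single one and 71 several. The edgeR step was tested on 20 sets of simulated data with the tested miRNAs, 40 of them changed. In these, 73% of 2-fold and 95.8% of 4-fold changes were recovered, 3.67% of calls were false, and simulations without changes gave 0 calls by edgeR on average, with 5.16% of unadjusted p below 0.05. The camera step was tested on another 20 sets with the miR-30 family shifted by −0.7 log2. Camera called that family in 100% of sets, and 0.714% of the lists without its entries. Counts were drawn independently for each miRNA, so these sets could not show how correlation within a list affects camera. In the edgeR sets, rises and falls were equal in number, and the simulated dispersion was the same in both genotypes. The recovery and false call rates therefore do not cover errors from scaling or from a library that stands apart. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.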

Results

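MicroRNAs (miRNAs) were profiled by small-RNA sequencing in the left ventricle of wild-type mice (WT, n = 3) and of mice carrying the R719W mutation in Myh6 (R719W, n = 3). Myh6 encodes the α-myosin heavy chain, the main myosin motor of the adult mouse ventricle, and mutations in cardiac myosin are a known cause of hypertrophic cardiomyopathy (HCM), an inherited thickening of the heart muscle. All 6 mice had received cyclosporin, an inhibitor of the phosphatase calcineurin, for 3 weeks, so the comparison is between genotypes under cyclosporin, and untreated mice were not analysed here. The labels call the libraries biological replicates. The tables listed 698 mature miRNAs, of which 387 had at least 1 read in the 6 libraries and 517 had too few reads to be tested. Levels are TMM-normalised CPM. Reads on miRNAs per library came to 817935, 765425 and 1192020 in WT replicates 1, 2 and 3, and to 1032928, 1168379 and 865845 in R719W replicates 1, 2 and 3. A count of 0 therefore allowed a level of up to 2.40 to 4.06 TMM-normalised CPM, depending on the library (3 reads). The reads carry no molecular identifiers, so intervals and floors cover counting error only.

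The libraries were dominated by a few miRNAs. miR-1, which is made in heart and skeletal muscle and restrains growth of muscle cells, took 51.2% ± 3.91 (SD, n = 3) of the reads in WT and 45.5% ± 5.10 (SD, n = 3) in R719W, with overlap between the libraries of the genotypes (exact permutation test, two-sided, p = 0.2). All muscle miRNAs together took 61.0% ± 4.63 in WT and 53.0% ± 5.04 in R719W (SD, n = 3, exact permutation p = 0.2). The 10 most abundant miRNAs took 79.3% ± 2.60 and 76.4% ± 2.70 (SD, n = 3, exact permutation p = 0.3). These 10 were miR-1, miR-208a, let-7i, miR-378, miR-125b-5p, let-7g, miR-143, miR-26a, let-7f and miR-29a. More miRNAs reached 10 reads in R719W (190.3 ± 5.13) than in WT (172 ± 7.0), and every R719W library lay above every WT library (SD, n = 3, exact permutation p = 0.1, the smallest p that 3 against 3 libraries can give). On the first principal component of the tested miRNAs, 60.3% of the variance, the genotypes lay apart. The second component, 23.9% of the variance, placed R719W replicate 1 at −5.13 and R719W replicates 2 and 3 at 4.36 and 2.64.

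**Figure D1:**
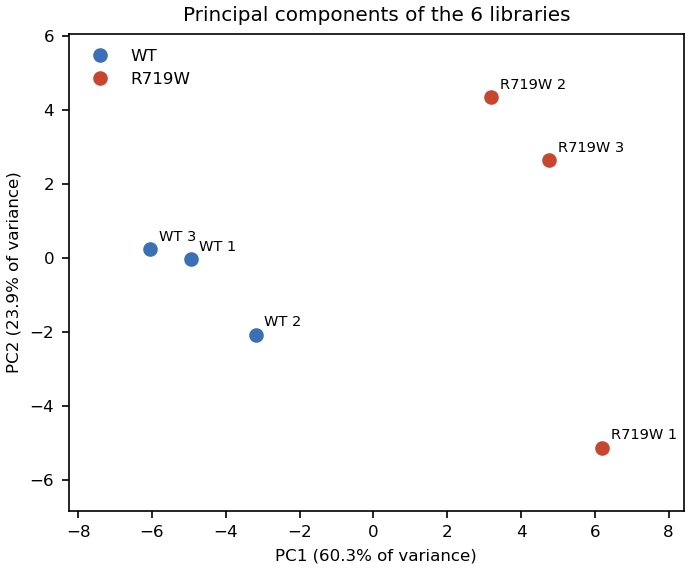
Principal components of TMM-normalised log2 CPM over the tested miRNAs; each point is 1 library, blue for WT and red for R719W, and the axes give component scores with the percent of variance of each. The WT and R719W libraries separate along the first axis (60.3% of the variance), and R719W replicate 1 lies apart from the other R719W libraries along the second (23.9%).

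The main question was which miRNAs differ between the R719W and WT left ventricles. miR-214, miR-199a-5p and miR-21, miRNAs known from activated fibroblasts and stressed hearts, rose and had the smallest p-values; the low-level miR-21* and miR-547, at 5.05-fold and 4.61-fold, rose more than miR-21. miR-214 rose 9.49-fold, from 92.2 ± 31.9 to 871 ± 167 CPM (SD, n = 3; log2 fold change 3.25, SE 0.28). miR-199a-5p rose 7.11-fold, from 14.4 ± 2.85 to 102.0 ± 12.4 CPM (SD, n = 3; log2 fold change 2.83, SE 0.26), and miR-21 rose 3.71-fold, from 315 ± 17.7 to 1169 ± 268 CPM (SD, n = 3; log2 fold change 1.89, SE 0.22). In the other direction, miR-499, which lies in an intron of the myosin gene Myh7b, fell from 14454 ± 1350 to 6576 ± 1243 CPM (SD, n = 3; log2 fold change −1.14, SE 0.20), and miR-378 and members of the miR-30 family fell as well.

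By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 36 of the miRNAs tested passed an adjusted p of 0.05, 23 higher and 13 lower in R719W. In each of the 36, the 3 values of one genotype all lay above the 3 of the other; among all miRNAs tested, 74 (40.9%) had no overlap, against 10% expected by chance for 3 against 3. Of the 36, 17 changed by more than 2-fold (13 higher and 4 lower). The split between rises and falls depended on the scaling: 12 higher and 15 lower with DESeq2's size factors, 34 and 3 with library totals alone, and 14 and 6 with totals without the 5 most abundant miRNAs. The log2 fold change of a miRNA differed from that of the TMM fit by a median of −0.11, 0.21 and 0.01 under these scalings. limma on the deposited CPM values, which also changes the test, the transform and the miRNAs tested, gave 30 and 2, with a median difference of 0.19. Every change below is relative to TMM. Across the 4 scalings of the counts, 14 miRNAs passed each time in the same direction, 11 higher (miR-214, miR-199a-5p, miR-21, miR-21*, miR-547, miR-674, miR-500, miR-411, miR-423-5p, let-7i and miR-125a-5p, the last chosen after its values were seen) and 3 lower (miR-499, miR-30e and miR-342-3p). The number of calls also rested on single libraries: it was 4, 20 and 4 without WT replicate 1, 2 or 3, and 56, 40 and 7 without R719W replicate 1, 2 or 3. miR-214, miR-199a-5p, miR-21 and miR-674 passed in each of these 6 fits.

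**Figure D2:**
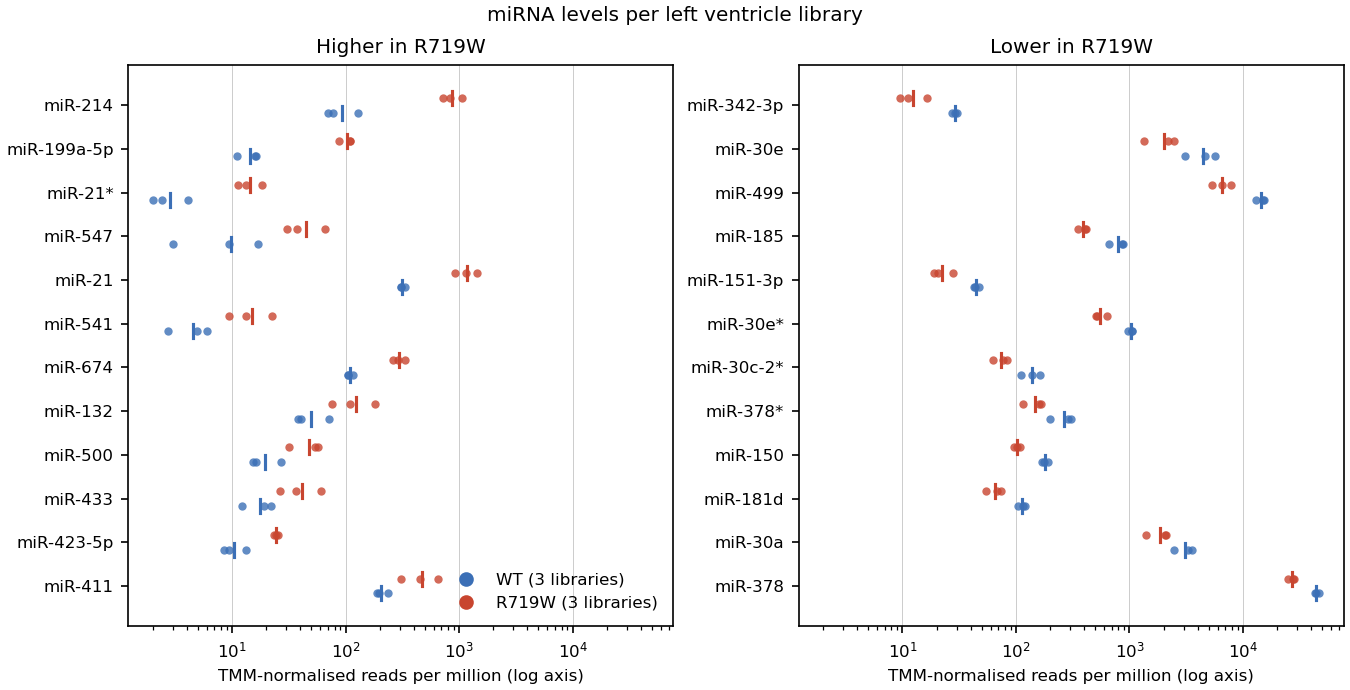
TMM-normalised CPM (log axis) of the 12 miRNAs with the largest positive and the 12 with the largest negative log2 fold change among those at an adjusted p below 0.05 (edgeR); each point is 1 library, blue for WT and red for R719W, and the vertical bars are means of 3 libraries. No R719W point overlaps the WT points of the same miRNA; miR-214 goes from a mean of 92.2 to 871 and miR-499 from 14454 to 6576.

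The other miRNAs with large rises were mostly of low level. miR-21*, the other arm of the miR-21 hairpin, rose from 2.84 ± 1.08 to 14.3 ± 3.72 CPM (SD, n = 3), and rested on 2 to 3 reads in each WT library. miR-547 rose from 9.86 ± 7.03 to 44.7 ± 18.8, miR-541 from 4.55 ± 1.70 to 15.03 ± 6.67, and miR-500 from 19.4 ± 6.45 to 47.4 ± 13.8 CPM (SD, n = 3). miR-674 rose 2.70-fold, from 109 ± 5.42 to 295 ± 35.4, miR-132 2.46-fold, miR-433 2.34-fold, miR-423-5p 2.30-fold and miR-411 2.28-fold (SD, n = 3). The abundant let-7i rose 2.16-fold, from 23527 ± 4368 to 50765 ± 15999 CPM (SD, n = 3; edgeR adjusted p = 0.0254). Adjusted p (edgeR, Benjamini-Hochberg) was 7.38e-05 for both miR-214 and miR-199a-5p, 4.02e-04 for miR-21, 0.00119 for miR-674 and 0.0137 for miR-21*. The hairpin of miR-214 lies on chromosome 1 at 162223368 to 162223477 (GRCm38, plus strand) and that of miR-199a-2 at 162217814 to 162217923, both within exons of the noncoding gene Dnm3os; miR-199a-5p (CCCAGTGTTCAGACTACCTGTTC) can also come from miR-199a-1 on chromosome 9. The miR-21 hairpin lies on chromosome 11 at 86584067 to 86584158 (minus strand), in an exon of Vmp1.

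Among the miRNAs that fell, miR-342-3p showed the largest decrease, from 28.97 ± 1.74 to 12.3 ± 3.57 CPM (SD, n = 3; log2 fold change −1.24, SE 0.29). miR-30e fell from 4445 ± 1295 to 2009 ± 589, miR-185 from 799 ± 123 to 392 ± 32.6 and miR-151-3p from 44.5 ± 2.74 to 22.4 ± 4.90 (SD, n = 3). miR-378, made from an intron of the metabolic coactivator gene Ppargc1b and abundant in heart, fell from 44407 ± 2077 to 26953 ± 1610 CPM, and its other arm, miR-378*, from 265 ± 56.8 to 147 ± 27.6 (SD, n = 3). miR-181d had a log2 fold change of −0.79 (SE 0.21). Adjusted p (edgeR, Benjamini-Hochberg) was 0.0254 for miR-342-3p and miR-378, 0.0258 for miR-30e and miR-151-3p, 0.0125 for miR-185 and 0.0325 for miR-378*. The calls for miR-378, miR-342-3p, miR-181d and miR-151-3p were each lost in 4 of the 6 fits that left out 1 library.

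Of the muscle miRNAs, 1 of the 5 tested fell and 4 did not pass, with the same count adjusted over the list alone. The member that fell was miR-499 (edgeR adjusted p = 0.00808), on chromosome 2 at 155622880 to 155622958 (plus strand). miR-208a, in an intron of Myh6 on chromosome 14 at 54949060 to 54949142 (minus strand), was the second most abundant miRNA, at 91514 ± 19938 CPM in WT and 61249 ± 16593 in R719W (SD, n = 3; log2 fold change −0.58, SE 0.26; edgeR adjusted p = 0.13). miR-208b, in an intron of Myh7, the gene of the slow β-myosin heavy chain, at 54975700 to 54975776 on the same strand, stood at 418 ± 90.5 and 664 ± 315 CPM (SD, n = 3; log2 fold change 0.67, SE 0.32; edgeR adjusted p = 0.156). miR-1 (log2 fold change −0.38, SE 0.25) and miR-133a (−0.15, SE 0.23, and 0.10 with library totals alone) did not pass. Neither the muscle list (median −0.38) nor the myosin intron list of miR-208a, miR-208b and miR-499 (median −0.58) was called by camera (adjusted p = 0.150 and 0.168). The miR-208a and miR-208b sequences are closely alike, and how reads near to both were divided is not given in the sources used here. The same holds for miR-199a-5p and miR-199b*, for miR-30a and miR-30e, and for members of the let-7 family.

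Fibroblast miRNAs were higher in R719W. Of the 4 tested entries, 3 rose and miR-199b* did not pass (log2 fold change 0.97, SE 0.35; edgeR adjusted p = 0.0819), and 4 rose when adjusted over the list alone. The entry for the 3' arm, whose sequence is shared by miR-199a and miR-199b, rose from 75.0 ± 14.6 to 137.6 ± 21.01 CPM (SD, n = 3; log2 fold change 0.87, SE 0.23). The list was called by camera with a preset correlation of 0.01 (median log2 fold change 1.90, adjusted p = 9.20e-06), and was not called with an estimated correlation (adjusted p = 0.186). With the preset correlation, camera also called 2 to 6 lists in each of the other 9 splits of the 6 libraries, which mix the genotypes. The wider list of miRNAs known to be raised in hypertrophic hearts, which holds the fibroblast entries, had 22 tested entries, of which 7 rose and 15 did not pass; 9 rose when adjusted over the list alone. They were miR-214, miR-199a-5p, miR-21, miR-21*, miR-132, the shared 3' arm entry and miR-23b, and 20 of the 22 entries had a positive log2 fold change (18 with DESeq2's size factors, 21 with library totals alone). This list was likewise called (median 0.72, camera adjusted p = 1.26e-05), but not with an estimated correlation (adjusted p = 0.186). miR-34a, another of its members, stood at 129.3 ± 14.1 CPM in WT and 122.6 ± 39.0 in R719W (SD, n = 3).

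miRNAs known to be lowered in hypertrophic hearts were lower in R719W. All 19 tested entries had a negative log2 fold change relative to TMM, 5 fell and 14 did not pass, and 6 fell when adjusted over the list alone (median −0.49, camera adjusted p = 6.38e-05; adjusted p = 0.241 with an estimated correlation). The 19 include all 10 tested entries of the miR-30 family, so the results of this list and of that family are not separate evidence. Outside the family, miR-150 alone passed. With library totals alone 6 of the 19 were positive, among them miR-29a, miR-29b, miR-93, miR-133a and miR-181b (0.12, 0.04, 0.01, 0.10 and 0.07). Of the 5 that fell, 4 belong to the miR-30 family, which is made by cardiomyocytes. miR-30 miRNAs are known to restrain connective tissue growth factor. That role is not attributed here to the other arms of their hairpins, marked by an asterisk. Such arms among the 4 calls were miR-30e* and miR-30c-2*, whose sequences start differently from those of miR-30a and miR-30e. In that family all 10 tested entries were negative, except 1, miR-30d, at 0.03 with library totals alone, with 4 calls and 6 adjusted over the list alone (median −0.70, camera adjusted p = 2.68e-04; adjusted p = 0.308 with an estimated correlation). miR-30e, miR-30e*, miR-30a and miR-30c-2* had log2 fold changes of −1.15 (SE 0.28), −0.90 (SE 0.18), −0.75 (SE 0.22) and −0.88 (SE 0.22). R719W replicate 1 carried part of the fall of the family relative to TMM, and most of the fall in its share of all reads. That share, which is not scaled by TMM, was 0.96% there. It was 1.61% and 1.69% in R719W replicates 2 and 3 and 1.72% to 1.77% in WT. Relative to TMM and without R719W replicate 1, miR-30b went from −0.70 to −0.39, miR-30c from −0.59 to −0.29 and miR-30d from −0.20 to −0.09. None of these was called in either fit. miR-30e, miR-30e*, miR-30a and miR-30c-2* still passed, at −0.97, −0.89, −0.62 and −0.82. Each of these 4 calls was lost in 3 of the 6 fits that left out 1 library. The fifth was miR-150, a lymphocyte miRNA, which fell from 179 ± 11.4 to 103 ± 6.85 CPM (SD, n = 3; edgeR adjusted p = 0.0254). The miR-29 family, known to repress collagen genes, had 0 of 4 tested entries called by edgeR, overall and adjusted over the list alone (camera adjusted p = 0.281). Its log2 fold changes were −0.08 (SE 0.25) for miR-29a, −0.16 (SE 0.20) for miR-29b, −0.49 (SE 0.20) for miR-29c and −0.29 (SE 0.51) for miR-29a*.

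miRNAs of the imprinted Dlk1-Dio3 region on chromosome 12, which are expressed in embryonic muscle and decline after birth, were higher in R719W. Of the 13 tested entries 12 had a positive log2 fold change, 5 rose and 8 did not pass, and 8 rose when adjusted over the list alone. The 5 were miR-411, miR-379, miR-376a, miR-433 and miR-541, with log2 fold changes of 1.19 (SE 0.28), 0.88 (SE 0.25), 0.89 (SE 0.24), 1.23 (SE 0.38) and 1.68 (SE 0.49). miR-411 was the most abundant of these, at 207 ± 27.3 CPM in WT and 473 ± 177 in R719W (SD, n = 3; edgeR adjusted p = 0.0254). The list was called by camera (median 0.88, adjusted p = 0.0112; adjusted p = 0.308 with an estimated correlation). Each of the 5 was no longer called in 4 or 5 of the 6 fits that left out 1 library.

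**Figure D3:**
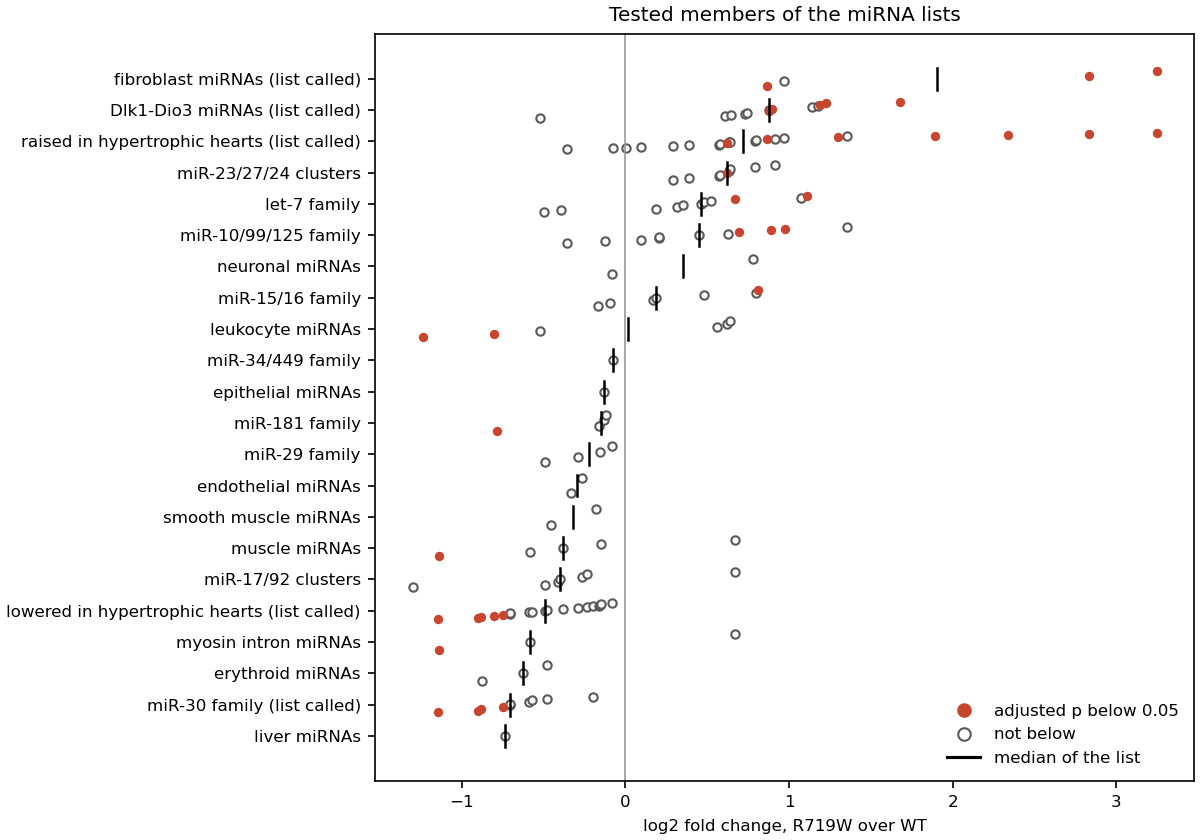
Log2 fold change (R719W over WT, TMM) of each tested member of the 22 lists; filled red points have an adjusted p below 0.05 (edgeR), open points do not, black bars are list medians, and the lists called by camera with a preset correlation are marked. The fibroblast list has the highest median (1.90), and all 10 entries of the miR-30 family lie below 0 (9 with library totals alone).

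Other families had few calls, and camera called none of them. In the let-7 family, 2 of 11 tested entries rose, let-7i and let-7e (the latter chosen after its values were seen), with 2 adjusted over the list alone (median 0.46, camera adjusted p = 0.326). let-7g and let-7f, with log2 fold changes of 0.48 (SE 0.30) and 0.46 (SE 0.33), turned to −0.0026 and −0.13 without R719W replicate 1, in which the let-7 family took 20.5% of the reads against 11.9% and 13.5% in R719W replicates 2 and 3; let-7i remained at 0.77 there (edgeR adjusted p = 0.00227). All 9 tested entries of the miR-23, miR-27 and miR-24 clusters were positive, of which miR-23b rose from 9614 ± 726 to 14764 ± 2179 CPM (SD, n = 3) and 8, miR-23a among them (log2 fold change 0.39, SE 0.21), did not pass; 0 passed edgeR adjusted over the list alone (camera adjusted p = 0.116). In the miR-10, miR-99 and miR-125 family 3 of 11 rose, also adjusted over the list alone (camera adjusted p = 0.209), while its abundant members miR-125b-5p (0.09, SE 0.18, and −0.01 with DESeq2's size factors) and miR-99a (0.21, SE 0.20) did not pass. In the miR-15 and miR-16 family 1 of 7 rose, 2 adjusted over the list alone (camera adjusted p = 0.358), with miR-16 at 0.17 (SE 0.21) and miR-322 at 0.19 (SE 0.17). In the miR-181 family 1 of 4 fell, miR-181d, also adjusted over the list alone (camera adjusted p = 0.209), with miR-181a at −0.12 (SE 0.20) and miR-181c at −0.13 (SE 0.19), both above 0 with library totals alone (0.12 and 0.09). The miR-17 and miR-92 clusters had 0 of 7 entries called by edgeR, overall and adjusted over the list alone (camera adjusted p = 0.150), with miR-93 at −0.23 (SE 0.26) and miR-20a at −0.49 (SE 0.25).

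Of the markers of cell types other than cardiomyocytes and fibroblasts, only miR-150 and miR-342-3p, lymphocyte miRNAs among the 6 tested leukocyte entries, passed, both lower. The general blood cell miRNA miR-142-3p stood at 578 ± 68.8 CPM in WT and 899 ± 192.4 in R719W (SD, n = 3; log2 fold change 0.64, SE 0.21; edgeR adjusted p = 0.0625). Adjusted over the list alone, 2 leukocyte entries were higher and 2 lower (camera adjusted p = 0.358). The 3 erythroid entries were all negative, with miR-486 at −0.62 (SE 0.29) and miR-451 at −0.48 (SE 0.34), and 0 passed edgeR, overall or adjusted over the list alone (camera adjusted p = 0.150). The endothelial miR-126-3p (−0.26, SE 0.21) and miR-126-5p (−0.33, SE 0.19) and the smooth muscle miRNAs miR-143 (−0.45, SE 0.25) and miR-145 (−0.18, SE 0.17, and 0.03 with library totals alone) did not pass. Neuronal, epithelial and liver markers had 4 tested entries between them, miR-128 (−0.08, SE 0.24), miR-138 (0.78, SE 0.47), miR-203 (−0.13, SE 0.18) and miR-194 (−0.73, SE 0.27). Of these, 0 passed edgeR adjusted over all miRNAs tested. miR-194 was the only tested liver entry, so adjustment over its list left its unadjusted edgeR p of 0.0219 as it was. miR-34a, the tested member of the miR-34 and miR-449 family, had a log2 fold change of −0.07 (SE 0.26). miR-26a, also among the 10 most abundant, did not pass (−0.27, SE 0.20).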

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

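Under each alternative in which they were tested, none of the 29 named and called miRNAs changed direction, while the number of calls did change. The cause was not tested except where fewer miRNAs or libraries entered the fit. The 36 calls became 20 with totals without the 5 most abundant miRNAs and 22 with a minimum of 100 reads in 3 libraries, where 101 miRNAs were tested; with the other settings there were 27 (DESeq2's size factors), 37 (library totals alone), 48 (no filter), 28 (DESeq2), and 32, 30 and 37 (limma with pseudocounts of 1, 0.5 and 10). Of the 29, 11 were called in each of these and the block fit wherever they had an adjusted p. They were let-7i, miR-199a-5p, miR-21, miR-21*, miR-214, miR-30e, miR-411, miR-499, miR-500, miR-547 and miR-674. Of these, miR-199a-5p, miR-21*, miR-500 and miR-547 had too few reads to be tested with the minimum of 100 reads in 3 libraries. Leaving out each library in turn gave 4 to 56 calls, fewest without WT replicate 1 or 3 (4 each) and most without R719W replicate 1 (56), and 5 to 6 called lists. With an estimated correlation camera called 0 lists (3 at an unadjusted p below 0.05), and fry called 7, adding the miR-15 and miR-16 family and the miR-23, miR-27 and miR-24 clusters. Replicate numbers did not pair the libraries (correlations of same-numbered deviations −0.19, −0.39 and 0.01, and 0 of 6 libraries closest to their own number); a replicate block gave 30 calls, 26 of them among the 36, and 5 lists. The direction turned only for named miRNAs that were not called. With library totals alone miR-29b went to 0.043, miR-133a to 0.10, miR-29a and miR-181a to 0.12, miR-93 to 0.0082, miR-181c to 0.095, miR-34a to 0.17, miR-145 to 0.031, miR-128 to 0.16 and miR-203 to 0.076. With limma at pseudocounts of 1, 0.5 and 10, miR-29b went to 0.038, miR-133a to 0.052, miR-29a and miR-181a to 0.083, miR-34a to 0.084 (0.085 at 10), miR-181c and miR-203 to 0.074 (0.073 at 10), miR-145 to 0.029 and miR-128 to 0.11 (0.10 at 10). Under library totals alone and these limma fits, log2 fold changes were higher than in the main fit by a median of 0.18 to 0.21 per miRNA. miR-125b-5p went to −0.014 both with DESeq2's size factors and with DESeq2. Over the fits without 1 library, miR-29a* ranged from −0.99 to 0.091, let-7g from −0.0026 to 0.61, let-7f from −0.13 to 0.65, miR-16 from −0.064 to 0.23, miR-34a from −0.39 to 0.12, miR-128 from −0.25 to 0.010, miR-29a from −0.37 to 0.041 and miR-125b-5p from −0.040 to 0.13. The shares of reads and the numbers of detected miRNAs kept their direction in all alternatives run for them. Both tables list the same miRNAs, so counting miRNAs of one table only as 0 changed nothing. Depth limits the low entries, since a count of 0 allows up to 2.40 to 4.06 TMM-normalised CPM per library.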

Other observations

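The tests of the ratio of miR-208b to miR-208a, the miR-199 and miR-214 entries, GC content, depth and the summed Dlk1-Dio3 reads were chosen after the results were seen. Those of genomic clusters, hairpin arms and splits were not. For the test of marker lists in R719W replicate 1, the lists were fixed beforehand. The choice of that library and of let-7 as its yardstick came from these results. Below the counts needed for testing, further miRNAs of the Dlk1-Dio3 region had more reads in R719W. The 35 untested entries with any read summed to 36.4 ± 7.12 CPM in WT and 84.9 ± 6.99 in R719W (SD, n = 3; 2.34-fold, and 2.68-fold by library totals alone or 2.16-fold with DESeq2's size factors; exact permutation p = 0.1, the smallest possible), with every R719W library above every WT library. Of the 35, 30 had more reads over the R719W libraries, 1 had fewer and 4 had as many. miR-382 had 38 against 6 reads, miR-376b 22 against 1 and miR-299* 22 against 2. R719W also had more reads in all (3067152 against 2775380). More miRNAs had at least 1 read there (318.7 ± 12.6 against 291.7 ± 6.03, SD, n = 3). The same count over all untested miRNAs was not made, so the 30 of 35 is not shown to be particular to this region. The other entries near the floor, named here after their values were seen, were miR-206, a skeletal muscle miRNA, with 9 reads in R719W and 0 in WT, and miR-34b-5p with 25 against 4. miR-1 and miR-133a, which are made from shared primary transcripts, stood far apart in level, with 2236 ± 296 reads of miR-1 per read of miR-133a in WT and 2015 ± 811 in R719W (SD, n = 3, exact permutation p = 0.8).

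Hairpins that neighbour each other in the genome changed alike. Among 130 hairpins with a single location, 44 lay in 17 clusters (same strand, within 10 kb). miR-199a-5p can come from more than 1 hairpin and was left out. miR-214 (log2 fold change 3.25) was therefore counted in no cluster, although miR-199a-2 lies within 10 kb of it. The mean difference in log2 fold change between cluster mates was 0.32, against 0.81 on average over 100000 random reassignments (permutation p = 1e-05, the smallest these can give). The reassignments drew from all 130 hairpins. Those outside clusters included larger changes, such as miR-21 (2.34 and 1.89 for its arms), than the highest in a cluster (1.23). Part of the gap can come from this wider pool. Of 40 simulated data sets with nothing shared, 3 passed 0.05, but all their hairpins came from 1 distribution, so they could not show this. In 14 of the 17 clusters all hairpins had log2 fold changes of one sign relative to TMM. The cluster of miR-99b, let-7e and miR-125a on chromosome 17 (17830188 to 17830879) had 4 of its 5 entries called higher, and miR-497 and miR-195 on chromosome 11 (70234717 to 70235135) had log2 fold changes of 0.81 and 0.80, of which the first passed. miR-30e and miR-30c-1 on chromosome 4 (120769534 to 120772697) had 2 of 3 entries called lower, and the pair of miR-144 and miR-451 had values of −0.88 and −0.48, neither called. The arms of 20 hairpins with both arms tested also moved together across hairpins (Pearson r = 0.79, permutation p = 7e-05; Spearman rho = 0.69, permutation p = 5e-04; r = 0.62 without miR-21 and miR-125a, the 2 farthest from the median on the arm at the lower genome coordinate, and 0.59 without miR-21 and miR-30e, the 2 farthest by the mean of both arms, a setting added after the data were seen), with the same sign in 15 of 20; hairpins are not independent replicates. The first result is consistent with shared primary transcripts and the second with shared precursors; precursor processing or a different mix of cells could give the agreement of arms as well, and these were not told apart by a test. The pairs that went apart included miR-339 (0.63 and −0.41) and let-7d (0.32 and −0.50), none of whose arms was called.

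On average, miR-208b moved against miR-208a, although neither was called alone and the genotypes overlapped for each. The log2 ratio of miR-208b to miR-208a was higher by 1.18 in R719W, from −7.77 ± 0.27 to −6.59 ± 0.51 (SD, n = 3), and higher in 3 of 3 R719W libraries than in any WT library (exact permutation p = 0.1, the smallest possible). There were 0.37 to 0.53 reads of miR-208b per 100 reads of miR-208a in WT and 0.77 to 1.52 in R719W. Opposite movement was not seen in each library. In R719W replicate 1, miR-208b (405 CPM) lay within the WT range (340 to 517 CPM). The ratio was higher there through low miR-208a (42643 CPM, against 69034 to 107057 CPM in WT). The ratio does not depend on library scaling, and misassignment of a fixed share of miR-208a reads would keep it equal between libraries. A shift in transcription from Myh6 to Myh7, the host genes of these miRNAs, is a candidate explanation; host gene mRNA was not analysed here.

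miR-199a-5p and miR-214 rose more than the miR-199b entries. The log2 fold change of miR-199b* was lower than that of miR-199a-5p by 1.86 (SE 0.43); this is the pattern itself, and miR-199b* from other cells could dilute a rise, so a larger share of fibroblast RNA with an unchanged profile stays open. The shared 3' arm entry rose less than miR-199a-5p by 1.96 (SE 0.34), likewise part of the pattern, and lay 0.10 (SE 0.42) below miR-199b*, which leaves reads shared between miR-199a and miR-199b as a candidate explanation of its small rise. The changes of miR-214 and miR-199a-5p differed by 0.42 (SE 0.38), consistent with output from their shared transcript, Dnm3os. A change within fibroblasts or in another cell that makes this transcript was not tested. The sequences of miR-199a-5p and miR-199b* are closely alike, and how reads near to both were divided is not given in the sources used here.

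R719W replicate 1 stood apart from R719W replicates 2 and 3, and leaving it out raised the calls from 36 to 56. Its let-7 entries lay above the genotype mean by a median log2 value of 0.64 and its miR-17 and miR-92 cluster entries (−0.51) and miR-30 family entries (−0.33) below it. Neither GC content of the mature sequence (Spearman rho = −0.043 with the deviation across miRNAs, which are not independent replicates) nor depth accounts for this, since its total of 1032928 reads lay within the range of the other 5 libraries. RNA of another cell type stays open. The erythroid entries lay above the genotype mean by a median of 0.47 and the leukocyte entries by 0.33, both above 0.5 times the let-7 deviation, the latter barely. Fibroblast, smooth muscle and endothelial entries lay at −0.13, −0.16 and −0.03. The erythroid median also varied between WT replicates 1, 2 and 3 (0.34, 0.08 and −0.42), while the leukocyte median there stayed within 0.03 of the WT mean. The erythroid miR-486 is also made in muscle, and a difference between mice stays open too.

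With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The 9 splits other than the real one each mix the genotypes. A genotype difference then widens the spread within their groups, which lowers the edgeR calls, while part of it stays between the groups. Their counts are therefore no measure of the calls to be had without any difference. The real split gave 36 calls by edgeR, and the highest of the other 9 was 0 (at most 19 at an unadjusted p below 0.05, and 0 by DESeq2); it was 1 of the 10 splits with as many. For the lists, the real split gave 5 calls by camera with the preset correlation, and each of the other 9 gave 2 to 6. In 3 of the 10 splits, the real one included, there were at least 5. The number of called lists therefore does not set the real split apart.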
